A study of Homo sapiens with 20 samples.

How the data were processed

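The deposited values are read counts per feature for 12 RNA-seq libraries, made by the authors with HTSeq 0.6.1 after alignment with Bowtie2 2.1.0 to hg19, as the submitters' processing notes say. Libraries were prepared with a stranded poly(A) kit. The strand setting of the counting, the gene annotation and the lowest mapping quality kept are not given in the sources used here. A gene that overlaps another on the opposite strand may therefore hold reads of both, and values of close paralogs such as LEFTY1 and LEFTY2, PRSS1 and PRSS3, the PCDHB family and the replication histones depend on how shared reads were handled. Reads set aside by the counting step came to 29.2% to 30.5% of each library for reads outside any feature, 19.3% to 22.2% for low mapping quality, 1.17% to 1.41% for ambiguous reads and 0.115% to 0.171% for reads not aligned. The files list 54435 features, of which 28251 had counts and 16792 were tested after edgeR's filterByExpr. The tested features comprised 15429 gene symbols, 285 LOC names and 225, 763 and 90 features of 3 kinds that carry only an assembly ID.

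The reference gene table is for GRCh38 while the counts were made on hg19, so it was used only to match names and to find which genes neighbour or overlap each other, and no positions are printed. It matched 15413 of the 16792 tested features by name. No feature carried any of the names DIGIT, GSC-DT, NR_144432 or LOC108868751, so the level of DIGIT was not analysed here and the knockout of each clone is taken from the labels. The 8 ChIP-seq samples of the series, SMAD3 and whole-cell extract, are not analysed here. Results that rest on certain withheld items are not reported here.

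Counts were scaled with edgeR's TMM factors, which lay between 0.937 and 1.05, and are given as CPM, each count divided by its library's scaled total and put on a common scale, as mean ± SD of 2 libraries unless another number is given. A quasi-likelihood model of edgeR was fitted to all 12 libraries with 6 groups, which leaves 6 residual degrees of freedom. KO stands for the mean of clones KO1 and KO2 with equal weight. Adjusted p values come from edgeR after Benjamini-Hochberg correction over the 16792 features with a threshold of 0.05. Standard errors (SE) of log2 fold changes are the size of the log2 fold change divided by the square root of the F statistic. The p values measure the spread between libraries of a clone, not between clones, and nothing in the labels says that replicates are separate cultures. A prior count of 2 was used only for CPM on the log scale, as in the principal components. Fitted log2 fold changes were left at edgeR's default prior count. For a gene at 0 counts in a group, the fold is given as a bound against a floor of 3 counts over the group, and for 1 to 3 counts the ratio carries its exact 95% counting interval.

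Before the data were examined, the comparisons, 27 gene lists for cell states, signalling pathways, cell processes and chromosome regions, the alternative settings and the rule for naming genes were fixed. Of the lists, 26 had members among the tested features. Lists were tested against all other genes with camera at its preset correlation of 0.01, adjusted over the lists measured, and again with an estimated correlation and with fry, which asks only whether a list's genes move one way on balance. The lists share genes, so their results are not independent of each other. Genes are named by a rule with 3 parts. The rule takes symbols past the threshold with at least 5 CPM in the higher group, a change of at least 1 (log2) in both clones in the direction of their mean and no overlap between the libraries compared, and keeps the 12 largest each way. It adds 17 lineage genes and the 2 largest called members each way of every list, and features with only an ID. The condition on overlap was not applied to the difference between days. Further members of a list are given where they belong to a group that is described by its count.

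Depth limits the precision of genes with few counts. The floor of 3 counts equals 0.14 to 0.302 CPM per library, and genes below about that level cannot be told from absent. Intervals and floors cover counting error only. In a test on simulated counts with 2 libraries a group, 66% to 86% of planted 2-fold changes and 86% to 100% of planted 4-fold changes were called, depending on the comparison, and false calls made up 2.31% to 9.71% of the calls. Software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and figures were drawn with matplotlib 3.10.9.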

Results

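Poly(A) RNA was sequenced from H1 cells, an established human embryonic stem cell line, either unedited (WT) or from 2 clones labelled as knockouts of DIGIT, a long noncoding RNA gene next to the homeobox gene GSC. Each line was sampled at day 0, in mTeSR1 medium for undifferentiated cells, and at day 4 of culture in RPMI with B27 and 50 ng/ml Activin A, a ligand of the TGF-beta family that directs these cells towards endoderm. The 6 groups of 2 libraries each make 12 libraries. Total counts per library were 10147526 and 13769250 in WT day 0, 17859275 and 21394547 in KO1 day 0, and 10477246 and 9942016 in KO2 day 0. At day 4 they were 13117737 and 15411604 in WT, 12374436 and 15351844 in KO1, and 12839236 and 15380017 in KO2. The 10 most counted features took 3.27% to 3.59% of a library.

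Day separated the libraries most. The first principal component held 71.9% of the variance and ran from −63.6 to −56.0 in the day 0 libraries and from 42.3 to 74.1 in the day 4 libraries. The components after it held 8.98% and 6.32% and spread WT, KO1 and KO2 apart at day 4. KO1 day 0 replicate 2 stood apart on the fourth component, at 33.3 against −21.6 to 5.52 in the other libraries, and the KO1 day 0 pair differed by a chi-square of 22.0 per gene where the other pairs differed by 1.96 to 4.11.

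Between day 0 and day 4, WT cells gained transcripts of the primitive streak and of definitive endoderm, and this comparison shows what the protocol did to unedited cells. CER1, a secreted antagonist of Nodal and BMP signals, rose from 1.49 ± 0.215 to 4032 ± 221 CPM (log2 11.41, SE 0.30, adjusted p = 4.3e-13). The endoderm transcription factors SOX17 and FOXA2 rose from 0.467 ± 0.161 to 138 ± 12.7 CPM and from 1.83 ± 0.116 to 60.6 ± 3.99 CPM. CXCR4, a chemokine receptor used as a surface marker of definitive endoderm, rose from 1.64 ± 0.0153 to 151.5 ± 17.2 CPM. The mesendoderm transcription factors EOMES and MIXL1 rose to 425 ± 89.3 and 59.6 ± 10.4 CPM, by log2 9.85 and 8.13. GATA6 had 1 count in the WT day 0 libraries together and 186 ± 17.1 CPM at day 4, a ratio of 4530 with a 95% counting interval of 812 to 179000. CD48, PRSS3 and ASB5 had 0 counts in WT at day 0 and were at least 162-fold, 141-fold and 79.3-fold higher at day 4, against a floor of 3 counts over the group. FGF17 and the WNT antagonist DKK1 rose by log2 10.68 and 8.48. Of the genes that fell, IDO1, which codes for a tryptophan-degrading enzyme, went from 109 ± 0.412 to 2.67 ± 0.325 CPM, and HES3, SEZ6 and NPTX1 fell by log2 −5.88, −5.96 and −5.54. BTBD17 fell to 1 count, a ratio of 201 with a 95% counting interval of 35.6 to 7990.

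The pluripotency factors moved apart in WT. SOX2 fell from 216 ± 23 to 111.6 ± 8.9 CPM (log2 −0.95, adjusted p = 5.53e-05), whereas NANOG rose from 25.8 ± 1.37 to 46.5 ± 1.88 CPM (log2 0.85, adjusted p = 4.05e-06). POU5F1, which codes for OCT4, went from 448 ± 15.9 to 384 ± 7.46 CPM (log2 −0.23, adjusted p = 0.0206). That small fall was not called without WT day 0 replicate 1 (adjusted p = 0.153), WT day 0 replicate 2 (0.0507), WT day 4 replicate 1 (0.143) or WT day 4 replicate 2 (0.0743), and ranged from 0.00647 to 0.153 over the alternatives. Among 29 measured pluripotency genes 6 rose, 20 fell and 3 did not pass, with the same counts adjusted over the list alone. DPPA2 fell by log2 −2.44 and the neuropeptide gene GAL rose by log2 2.35. The list was called lower than other genes (adjusted p = 0.000989), a call lost at adjusted p = 0.106 with an estimated correlation.

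In all, 8332 of 16792 features passed in WT, 4075 higher and 4257 lower at day 4, and 3080 of them changed by at least 1 (log2). With upper-quartile factors in place of TMM, 3619 were higher and 4719 lower. Of 20 measured primitive streak and mesendoderm genes 18 rose and 1 fell, as they did adjusted over the list alone. Their median log2 change was 5.97, or 5.41 with genes at 0 counts set to their bound. Of 41 measured definitive endoderm genes 36 rose, 2 fell and 3 did not pass, also adjusted over the list alone, with a median of 3.98. Nodal and Activin pathway genes included 19 of 26 that rose, BMP targets 15 of 18, WNT pathway genes 17 of 26 and genes of adhesion and epithelial-mesenchymal transition 19 of 28. Adjusted over the list alone these counts were 19, 15, 17 and 20. GREM1, DKK4 and the cadherin CDH2 rose by log2 4.89, 7.04 and 3.49 in these lists, and the claudin CLDN4 fell by log2 −1.80. All 6 of these lists were called higher by camera and stayed so with an estimated correlation, at adjusted p = 0.00374 to 0.0266.

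Further WT lists were called at the preset correlation alone. Cholesterol synthesis genes fell in 17 of 19 cases (17 lower and 1 higher adjusted over the list alone), among them INSIG1 at log2 −1.72, with adjusted p = 0.000854, and adjusted p = 0.422 with an estimated correlation. FGF pathway genes rose in 9 and fell in 6 of 22 cases, both also adjusted over the list alone, with FGF8 at log2 7.27 and FGF19 at log2 −2.23 (adjusted p = 0.000989, and adjusted p = 0.18 with an estimated correlation). Cell cycle genes rose in 15 of 25 cases and stress response genes in 13 of 22, with 1 lower in each and the same counts adjusted over the list alone. Their calls were lost at adjusted p = 0.437 and 0.246 with an estimated correlation. Mesoderm genes rose in 11 and fell in 4 of 21 cases, and neuroectoderm genes rose in 6 and fell in 11 of 25, and neither list was called (adjusted p = 0.137 and 0.155).

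**Figure D1:**
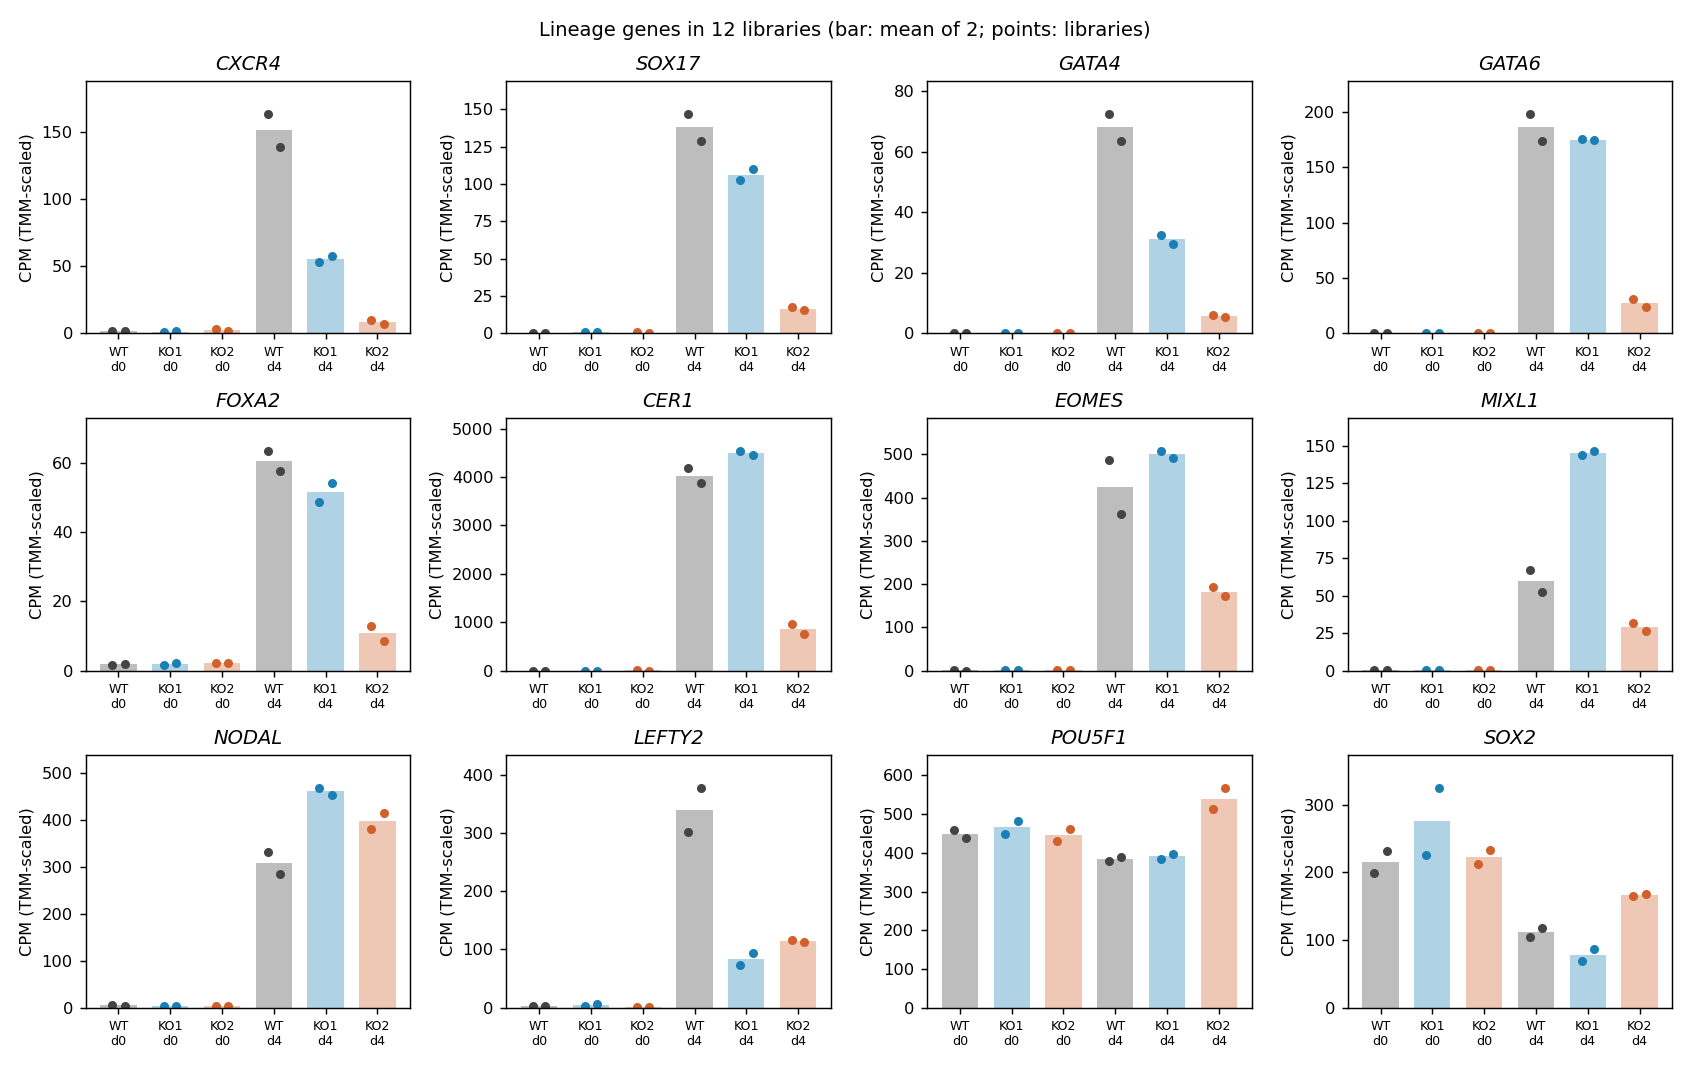
CPM values, scaled by TMM, of 12 lineage genes in each of the 6 groups; bars are means of 2 libraries and points are the libraries. CXCR4 stood at 151.5 CPM in WT, 55.6 CPM in KO1 and 8.56 CPM in KO2 at day 4.

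At day 4 both clones were compared with WT to ask what loss of DIGIT, as labelled, did to the endoderm programme. CXCR4 was 151.5 ± 17.2 CPM in WT, 55.6 ± 3.51 CPM in KO1 and 8.56 ± 2.08 CPM in KO2, and was lower in the mean of the clones by log2 −2.80 (SE 0.11, adjusted p = 6.22e-10). GATA4, an endoderm transcription factor, was 68.1 ± 6.32, 31.1 ± 2.15 and 5.69 ± 0.574 CPM, and was lower by log2 −2.36 (SE 0.10, adjusted p = 6.22e-10). The Nodal antagonists LEFTY1 and LEFTY2 were lower by log2 −1.48 and −1.79, with LEFTY2 at 339 ± 53.3 CPM in WT, 84.0 ± 14.8 in KO1 and 115 ± 1.99 in KO2. T, the brachyury gene of the primitive streak, was higher by log2 0.88 (SE 0.14, adjusted p = 0.00028), with 13.4 ± 1.6 CPM in WT, 27.8 ± 1.62 in KO1 and 22.0 ± 3.28 in KO2. NODAL was higher by log2 0.48 (adjusted p = 0.00165), at 308 ± 33.2 CPM in WT, 461.5 ± 9.62 in KO1 and 399 ± 23.6 in KO2. The NODAL call was lost without WT day 4 replicate 2, at adjusted p = 0.0662, the highest over the alternatives, of which the lowest was 1.81e-08.

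SOX17, GATA6, FOXA2, HHEX, GSC and CER1 were also lower in the mean of the clones, by log2 −1.72, −1.42, −1.37, −1.60, −1.52 and −1.03, and these means rested mainly on KO2. GSC, the gene beside DIGIT, was 51.0 ± 7.64 CPM in WT, 37.1 ± 0.621 in KO1 and 8.53 ± 0.421 in KO2 (adjusted p = 9.93e-06). SOX17 was 138 ± 12.7, 106 ± 5.32 and 16.5 ± 1.54 CPM, and CER1 was 4032 ± 221, 4490 ± 64.8 and 866 ± 143 CPM. EOMES was lower by log2 −0.49 (adjusted p = 0.00339) and POU5F1 higher by log2 0.26 (adjusted p = 0.00886), while NANOG, SOX2 and MIXL1 did not pass in the mean (adjusted p = 0.0643, 0.887 and 0.41), SOX2 and MIXL1 having opposite signs in the clones. Without WT day 4 replicate 1 the calls of EOMES and POU5F1 were lost at adjusted p = 0.154 and 0.125, and without WT day 4 replicate 2 that of POU5F1 at 0.0631. NANOG was called without KO1 day 0 replicate 1 (adjusted p = 0.021) and without KO1 day 0 replicate 2 (0.0209). With the 4 KO libraries of day 4 as 1 group, whose spread then holds the difference between clones, the calls of these 6 genes, EOMES and POU5F1 were lost (adjusted p = 0.17 for GSC to 0.636 for EOMES, whose lowest values over the alternatives were 8.34e-36 and 4.33e-09). CXCR4, GATA4, LEFTY1, LEFTY2, T and NODAL kept theirs. This setting counts the 4 libraries as independent although they come from 2 clones, so a kept call does not show how further clones would behave.

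Definitive endoderm genes were lower as a group in the mean of the clones at day 4. Of 41 measured, 36 were lower, 1 was higher and 4 did not pass (37 lower and 1 higher adjusted over the list alone), with a median of log2 −1.36 and adjusted p = 3.68e-77, and adjusted p = 0.00473 with an estimated correlation. The cholecystokinin receptor gene CCKBR went from 144 ± 17.3 CPM in WT to 19.5 ± 0.777 in KO1 and 8.01 ± 0.923 in KO2, and the apolipoprotein gene APOA2 had 3 counts in KO2 at day 4, 56.5-fold below WT with a 95% counting interval of 19 to 276. In KO1 alone 21 were lower and 1 higher (24 and 1 adjusted over the list alone), with a median of log2 −0.46 and a list call lost at adjusted p = 0.0599 with an estimated correlation. In KO2 alone 36 were lower and 1 higher (37 and 1 adjusted over the list alone), with a median of log2 −2.16 and adjusted p = 0.00259 with an estimated correlation. FST, an Activin-binding protein gene, was the member that was higher, by log2 0.53, with a KO1 value near that of WT (45.9 ± 0.563 CPM in WT, 46.5 ± 2.97 in KO1, 94.8 ± 11.7 in KO2). The FST call was lost with the 4 KO libraries as 1 group, at adjusted p = 0.169.

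Cholesterol synthesis genes were higher in the mean of the clones in all 19 measured cases, also adjusted over the list alone, with a median of log2 0.90 (adjusted p = 6.49e-36, and adjusted p = 0.0217 with an estimated correlation). That mean rested mainly on KO1, with medians of log2 1.83 in KO1 and 0.10 in KO2. HMGCS1, an enzyme early in that pathway, was 532 ± 39.6 CPM in WT, 2775 ± 78.1 in KO1 and 756 ± 115 in KO2. INSIG1, a sterol-regulated inhibitor of SREBP processing, was 33.9 ± 3.28, 260.5 ± 28.8 and 36.2 ± 8.01 CPM, and its call was lost with the 4 KO libraries as 1 group (adjusted p = 0.09).

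The lists that follow were called at day 4 at the preset correlation and not with an estimated one. Pluripotency genes were higher in 9 and lower in 2 of 29 cases (12 and 3 adjusted over the list alone), with the transcription factors TFAP2C and ZFP42 higher by log2 1.24 and 0.84 (adjusted p = 0.214 with an estimated correlation). Primitive streak genes were higher in 3 and lower in 7 of 20 cases, the same adjusted over the list alone, with FGF17 lower by log2 −1.92 (adjusted p = 0.302 with an estimated correlation). These means join clones whose medians had opposite signs, at log2 −0.11 in KO1 and 0.42 in KO2 for pluripotency genes and 0.38 and −0.59 for primitive streak genes. Higher and lower pluripotency genes numbered 4 and 4 in KO1 (5 and 7 adjusted over the list alone) and 18 and 3 in KO2, and primitive streak genes 7 and 3 in KO1 (8 and 4 adjusted over the list alone) and 2 and 13 in KO2. No call of either list against WT held in a clone with an estimated correlation (pluripotency adjusted p = 0.89 in KO1 and 0.058 in KO2, primitive streak 0.369 and 0.058). WNT pathway genes were higher in 4 and lower in 8 of 26 cases (4 and 9 adjusted over the list alone), with LEF1 and WNT5A higher by log2 1.97 and 1.17 and LGR5 and FRZB lower by log2 −2.71 and −2.36 (adjusted p = 0.101 with an estimated correlation). BMP targets were higher in 2 and lower in 7 of 18 cases, with BMP7 lower by log2 −1.51 and GREM1, a BMP antagonist, higher by log2 1.12 (adjusted p = 0.167 with an estimated correlation). Genes of adhesion and epithelial-mesenchymal transition were higher in 5 and lower in 8 of 28 cases (8 and 8 adjusted over the list alone), with KRT8 and the basement membrane collagen COL4A1 lower by log2 −1.17 and −1 and the cadherin CDH11 higher by log2 1.18. Their median was 0.01 while camera called them lower (adjusted p = 0.302 with an estimated correlation). Stress response genes were higher in 6 and lower in 1 of 22 cases (7 and 1 adjusted over the list alone), with the serine synthesis gene PSAT1 higher by log2 0.61 (adjusted p = 0.167 with an estimated correlation).

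FGF pathway genes at day 4 were higher in 6 and lower in 8 of 22 cases (7 and 8 adjusted over the list alone; adjusted p = 0.0332, and adjusted p = 0.302 with an estimated correlation). Hypoxia and glycolysis genes were higher in 8 and lower in 2 of 19 cases (9 and 2 adjusted over the list alone), with hexokinase HK2 higher by log2 0.70 (adjusted p = 0.302 with an estimated correlation). Later endoderm and hepatic genes were higher in 2 and lower in 5 of 17 cases (3 and 7 adjusted over the list alone), with APOA1 lower by log2 −3.94 (adjusted p = 0.101 with an estimated correlation). Markers of other lineages showed no call in the mean of the clones, which lay on opposite sides of WT in mesoderm genes (medians of log2 0.88 in KO1 and −0.46 in KO2). In the mean, mesoderm genes were higher in 4 and lower in 3 of 21 cases (adjusted p = 0.403) and neuroectoderm genes were higher in 5 and lower in 2 of 25 cases (adjusted p = 0.203). The Nodal and Activin pathway list, which holds LEFTY1 and LEFTY2, was not called either, with 3 higher and 7 lower of 26 (adjusted p = 0.348).

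The largest changes common to both clones at day 4 lay partly outside these lists. PKIB, a protein kinase A inhibitor gene, was 11.15 ± 1.74 CPM in WT, 107 ± 3.4 in KO1 and 54.96 ± 1.72 in KO2 (log2 2.77, SE 0.12, adjusted p = 8.92e-10). The mitochondrial protein gene CHCHD2 was higher by log2 1.83, FGF19 by log2 1.51, the WNT regulator DACT1 by log2 1.43, the clock gene PER3 by log2 1.39 and the hyaluronan receptor CD44 by log2 1.36. VWF, which codes for von Willebrand factor, was 62.9 ± 5.46 CPM in WT, 9.98 ± 1.55 in KO1 and 1.80 ± 0.746 in KO2 (log2 −3.90, SE 0.16, adjusted p = 6.22e-10). The iron exporter gene SLC40A1, TMEM150C, COLEC12 and the endoderm noncoding RNA LINC00261 were lower by log2 −3.16, −3.08, −2.88 and −2.81. LRRC61 had 3 counts in KO1 at day 4, 60.8-fold below WT with a 95% counting interval of 20.5 to 298, and C7orf29, which overlaps it, was lower by log2 −3.99. PCDHB5, a clustered protocadherin gene, was lower by log2 −3.88.

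In total 1902 features were higher and 2109 lower in the clones than in WT at day 4, and 163 and 458 of these by at least 1 (log2). The count of higher features was 637 without WT day 4 replicate 1, 901 without WT day 4 replicate 2, 1256 without KO2 day 4 replicate 1, 2897 without KO1 day 0 replicate 1 and 2902 without KO1 day 0 replicate 2, and that of lower features was 1114 without WT day 4 replicate 1. With the 4 KO libraries as 1 group the counts were 779 and 954, and in a fit of only the day 4 libraries compared they were 3055 and 3225.

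Each clone was then set against WT at day 4, and KO2 against KO1, to see how far the clones act alike. KO2 was lower than WT in CXCR4 by 17.8-fold, in GATA4 by 12-fold, in SOX17 by 8.38-fold and in GATA6 by 6.74-fold, and lower in EOMES, MIXL1, FOXA2, HHEX, GSC and CER1 by log2 −1.03 to −2.74. KO1 was lower than WT in CXCR4 by log2 −1.44, GATA4 by log2 −1.13, LEFTY1 by log2 −1.42 and LEFTY2 by log2 −2.01, and higher in MIXL1 by log2 1.29, T by log2 1.05 and NODAL by log2 0.58. KO2 was higher than WT in POU5F1 by log2 0.49, NANOG by log2 0.41, SOX2 by log2 0.58, T by log2 0.72 and NODAL by log2 0.37 (adjusted p = 0.00018, 0.00405, 0.00716, 0.00281 and 0.0156).

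Some calls of lineage genes against WT turned on single libraries. In KO2 the call of NANOG was lost without WT day 4 replicate 2 (adjusted p = 0.0575), that of SOX2 without WT day 4 replicate 1 (0.0997), that of T without WT day 4 replicate 2 (0.0547) or KO2 day 4 replicate 2 (0.065), and that of NODAL without WT day 4 replicate 2 (0.206) or KO2 day 4 replicate 2 (0.146). Their lowest values over the alternatives were 0.000199, 4.48e-09, 4.62e-05 and 0.000188. SOX2 and SOX17 were lower in KO1, by log2 −0.52 and −0.37 (adjusted p = 0.0216 and 0.0413). The SOX2 call was lost without WT day 4 replicate 1 (adjusted p = 0.0511), WT day 4 replicate 2 (0.151) or KO1 day 4 replicate 1 (0.23), with a lowest value of 1.1e-06 over the alternatives. That of SOX17 was lost without WT day 4 replicate 1 or 2 (0.281 and 0.0661), KO1 day 4 replicate 1 or 2 (0.267 and 0.122) or KO2 day 4 replicate 1 or 2 (0.053 and 0.0596), with a lowest value of 0.000466. GATA6, CER1, FOXA2 and EOMES did not pass in KO1 (log2 −0.09, 0.16, −0.23 and 0.24), although EOMES was called without WT day 4 replicate 1 (adjusted p = 0.0396). GSC and HHEX in KO1, at log2 −0.46 and −0.47, had adjusted p = 0.0986 and 0.0975. They were called without KO1 day 0 replicate 1 (adjusted p = 0.000859 and 0.000665) or replicate 2 (0.000838 and 0.000693), and adjusted p for GSC ranged from 0.000838 to 0.608 over the alternatives.

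Tested directly at day 4, KO2 lay below KO1 in definitive endoderm genes, with 32 of 41 lower and 1 higher (33 and 1 adjusted over the list alone), a median of log2 −1.46 and adjusted p = 0.00645 with an estimated correlation. It lay below KO1 in 14 of 20 primitive streak genes (16 adjusted over the list alone), with a median of log2 −1.34 and adjusted p = 0.0111 with an estimated correlation. KO2 was higher than KO1 in 16 of 29 pluripotency genes and lower in 2 (18 and 2 adjusted over the list alone), with a median of log2 0.45 and adjusted p = 0.0177 with an estimated correlation.

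Mesoderm and sterol genes marked KO1. Against WT, 10 of 21 mesoderm genes were higher in KO1 and none lower, also adjusted over the list alone (median log2 0.88, adjusted p = 1.75e-08, and adjusted p = 0.0464 with an estimated correlation), among them COL3A1 by log2 2.08 and PDGFRB by log2 1.12. In KO2, 8 were lower than in WT and none higher (adjusted p = 0.0198, and adjusted p = 0.224 with an estimated correlation). KO2 lay below KO1 in 15 of 21 mesoderm genes, with a median of log2 −1.80 and adjusted p = 0.00865 with an estimated correlation. All 19 cholesterol synthesis genes were higher in KO1 than in WT, with a median of log2 1.83 (adjusted p = 2.55e-114, and adjusted p = 0.0017 with an estimated correlation). In KO2 5 were higher and 1 lower, with a median of log2 0.10 (adjusted p = 0.27), and all 19 were lower in KO2 than in KO1, with a median of log2 −1.59. HMGCS1, INSIG1 and the squalene epoxidase gene SQLE were higher in KO1 by log2 2.38, 2.94 and 1.51. BMP targets and genes of adhesion and epithelial-mesenchymal transition lay lower in KO2 than in KO1 in 8 of 18 and 17 of 28 cases, with medians of log2 −0.51 and −0.48 (adjusted p = 0.044 and 0.0335 with an estimated correlation).

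**Figure D2:**
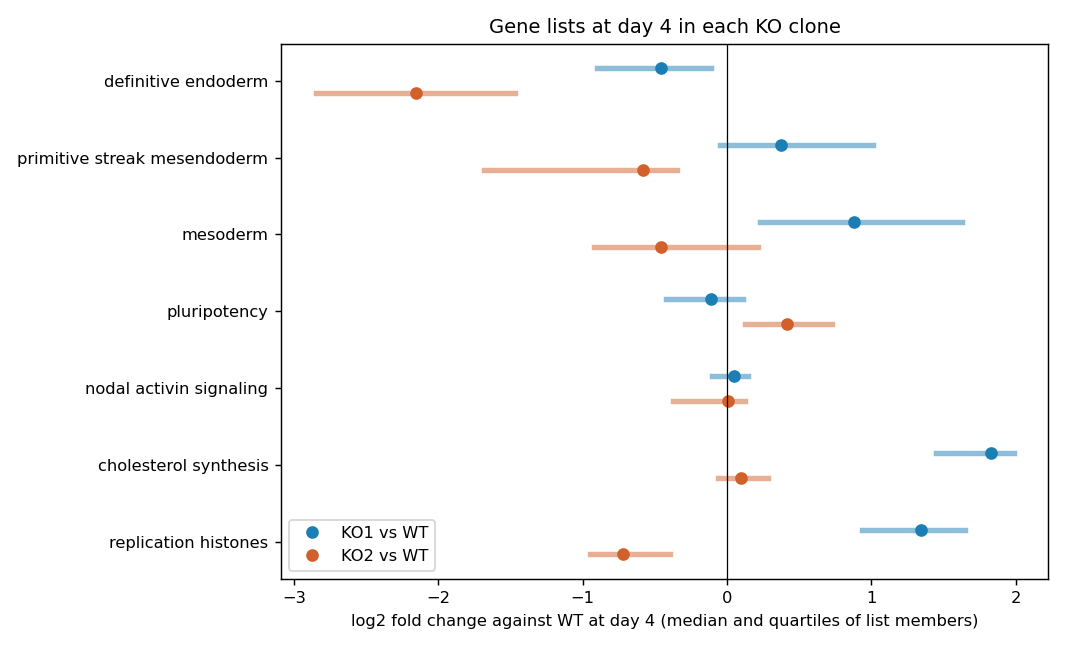
Median and quartiles of the log2 fold change against WT at day 4 for the measured members of 7 gene lists, in KO1 and in KO2. Cholesterol synthesis genes had medians of 1.83 in KO1 and 0.10 in KO2, and definitive endoderm genes −0.46 and −2.16.

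By count, 3337 features differed from WT at day 4 in KO1, 4697 in KO2, and 4214 between the clones. Called in both clones were 633 higher and 831 lower, against 237 and 229 for independent lists of these sizes, and 188 were called in opposite directions. Across genes, which are not independent replicates, the changes of the clones had Pearson's r of 0.439, against a mean of 0.492 in 40 simulations where the clones shared only their WT libraries. The simulations gave a mean of 0 features called in both, and a covariance of 0.0479 against 0.154 observed. In them neither clone had changes of its own, with means of 0.55 features called in KO1 and 0.425 in KO2. An overlap of 0 follows from that setting. It does not show how many joint calls would arise from unrelated changes of the clones together with shared WT libraries. Part of the common changes may come from the shared WT libraries. The KO1 count was 5228 without either KO1 day 0 library, 1658 and 1812 without WT day 4 replicate 1 or 2, and 1353 and 1799 without KO1 day 4 replicate 1 or 2. The KO2 count was 2492 without WT day 4 replicate 1 and 2859 and 2499 without KO2 day 4 replicate 1 or 2, and the count between clones was 2146 and 2789 without KO1 day 4 replicate 1 or 2, and 2667 and 2285 without KO2 day 4 replicate 1 or 2.

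At day 0 the clones were compared with WT to see what set them apart before differentiation. None of the 17 lineage genes passed, although SOX2, GSC and HHEX were called without KO1 day 0 replicate 1 (log2 0.32, 2.27 and 1.21). That fit leaves replicate 2, the library that stood apart, as the only KO1 library of day 0. In KO1 replicates 1 and 2, GSC had 6 and 35 counts, HHEX 19 and 68 counts, and SOX2 226 and 324 CPM. In WT, GSC had 1 and 4 counts and HHEX 6 and 10. PKIB was 23.1 ± 0.154 CPM in WT, 84.5 ± 13.2 in KO1 and 79.8 ± 7.06 in KO2 (log2 1.83, SE 0.11, adjusted p = 4.8e-07). The imprinted genes MEG3 and PEG3 were lower by log2 −4.16 and −3.29, with MEG3 at 8.10 ± 1.33 CPM in WT, 0.336 ± 0.224 in KO1 and 0.630 ± 0.494 in KO2. PIWIL2, a germline PIWI gene, was lower by log2 −2.09 (adjusted p = 3.21e-05), and the zinc finger genes ZNF585B and ZNF558 were lower by log2 −1.88 and −1.48. PCDHB5 was 19.2 ± 1.7 CPM in WT, 2.67 ± 0.125 in KO1 and 1.96 ± 0.277 in KO2. LRRC61 was lower by log2 −3.85, to 0.221 ± 0.00193 CPM in KO1 and 2.60 ± 0.759 in KO2, from 11.22 ± 2.48 in WT. TEK, an angiopoietin receptor gene, was lower by log2 −1.23 (adjusted p = 0.000506), a call lost with the 4 KO libraries as 1 group (adjusted p = 0.153), as was that of LRRC61 (adjusted p = 0.159), with lowest values over the alternatives of 9.46e-25 for TEK.

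CDKN1A, which codes for the cell cycle inhibitor p21, was lower at day 0 by log2 −1.21 (28.2 ± 0.927 CPM in WT, 11.1 ± 1.37 in KO1, 13.6 ± 3 in KO2; adjusted p = 0.00137). NPTX1 was higher by log2 1.58 (adjusted p = 0.0162) and S100A6 by log2 1.21 (adjusted p = 0.00509). Without WT day 0 replicate 1 the calls of CDKN1A, NPTX1 and S100A6 were lost at adjusted p = 0.062, 0.345 and 0.0724, and without WT day 0 replicate 2 at 0.0591, 0.464 and 0.342. That of NPTX1 was also lost without KO2 day 0 replicate 1 (0.071) or replicate 2 (0.0514). With the 4 KO libraries as 1 group, adjusted p was 0.648, 0.117 and 0.269 for these 3 genes, with lowest values over the alternatives of 2.57e-20, 8.47e-38 and 2.31e-09.

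Among the groups given here at day 0, of 13 germ cell genes 1 was lower (4 adjusted over the list alone), with a median of log2 −0.18 (adjusted p = 5.74e-06, and adjusted p = 0.0246 with an estimated correlation). The clones were unlike in this list, with medians of log2 −0.04 in KO1 and −0.35 in KO2. Hypoxia and glycolysis genes, with 0 of 19 called and 4 higher adjusted over the list alone, had a median of log2 0.19 and a list call that was lost at adjusted p = 0.0533 with an estimated correlation. Imprinted genes had 2 of 21 lower, MEG3 and PEG3, also adjusted over the list alone, and a list call lost at adjusted p = 0.0533 with an estimated correlation. Definitive endoderm genes had 0 of 41 called at day 0 (3 higher and 1 lower adjusted over the list alone), a median of log2 0.16 and adjusted p = 0.00831, and adjusted p = 0.525 with an estimated correlation. Cholesterol synthesis genes (0 of 19 called), genes of chromosome 20q11 (1 of 20 higher, 5 adjusted over the list alone) and of 12p (0 of 39 called, 2 lower adjusted over the list alone) had list calls lost at adjusted p = 0.515, 0.299 and 0.118 with an estimated correlation.

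Counts at day 0 were small and turned on single libraries. There were 15 features higher and 32 lower in the clones, 47 in all, with 1251 at an unadjusted p under 0.05. Without the filter on low counts 124 were higher and 108 lower, so that the larger part was then higher. The total was 12 without WT day 0 replicate 1 or 2, 21 and 25 without KO2 day 0 replicate 1 or 2, 1657 without KO1 day 0 replicate 1 and 155 without KO1 day 0 replicate 2. Called in both clones were 6 higher and 14 lower and 0 in opposite directions, against simulated means of 0 and 0.025 with shared WT libraries. The simulated clones again had no changes of their own, so these means do not show what unrelated changes would share.

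**Figure D3:**
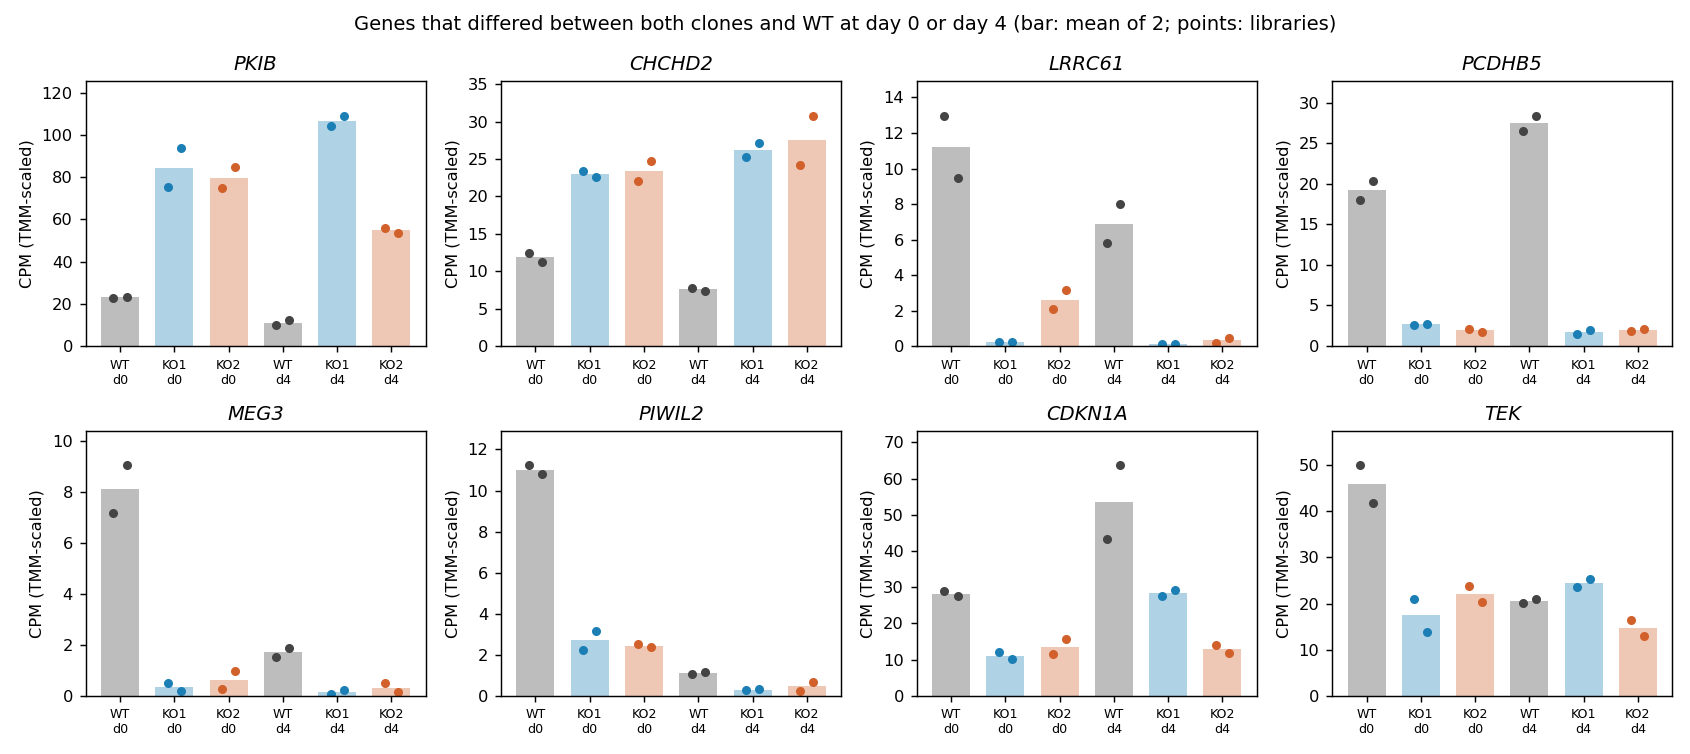
CPM values, scaled by TMM, of 8 genes that differed between both clones and WT at day 0 or day 4; bars are means of 2 libraries and points are the libraries. PKIB stood at 23.1 CPM in WT, 84.5 CPM in KO1 and 79.8 CPM in KO2 at day 0.

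The effect of the knockout label at day 4 was tested against that at day 0, to separate changes in the response from differences already there. DACT1, CD44, the actin-bundling protein gene LCP1, the collagen gene COL12A1 and NRK gained in the clones relative to WT, by log2 1.69, 1.66, 1.77, 1.73 and 1.69. VWF, CCKBR, TMEM150C, FAM184A, CXCR4 and CXCR7 lost ground, by log2 −3.86, −3.69, −3.58, −3.02, −3.03 and −3.23. FOXA2 did so in the mean of the clones, by log2 −1.52, with a call in KO2 (log2 −2.77, adjusted p = 0.000174) and none in KO1 (log2 −0.27, adjusted p = 0.65). GSC and HHEX were also called, but the size of their difference rests on few day 0 counts, 1 and 4 for GSC and 6 and 10 for HHEX in WT, and 6 and 35 for GSC and 19 and 68 for HHEX in KO1, where the larger count is that of replicate 2. CXCR4, for one, had adjusted p = 2.39e-05, and with the 4 KO libraries as 1 group 0.334, with a lowest value over the alternatives of 2.8e-26. That setting also ended the calls of VWF, LCP1, COL12A1, NRK, CXCR7, GSC, HHEX and FOXA2, at adjusted p = 0.0747, 0.0752, 0.0602, 0.0762, 0.164, 0.324, 0.333 and 0.617. Definitive endoderm genes responded less in 28 of 41 cases and more in none (36 lower adjusted over the list alone), with a median of log2 −1.37 and adjusted p = 0.0417 with an estimated correlation. That mean rested mainly on KO2, with 31 of 41 lower and a median of log2 −2.12 (35 lower and 1 higher adjusted over the list alone; adjusted p = 0.0223 with an estimated correlation). KO1 had 14 lower and a median of log2 −0.68 (18 adjusted over the list alone; adjusted p = 0.157 with an estimated correlation), and SOX17, FOXA2, GATA4, GATA6 and CER1 were called in KO2 and not in KO1, with 0 to 17 counts per day 0 library behind SOX17, GATA4 and GATA6. LEFTY1 and LEFTY2 went the other way. Their smaller response was called in KO1 (log2 −1.87 and −2.46, adjusted p = 0.0201 and 0.00175) and not in KO2 (log2 −0.56 and −0.83, adjusted p = 0.643 and 0.359). The KO1 day 0 counts behind it were 25 and 109 for LEFTY1 and 39 and 127 for LEFTY2, the larger again in replicate 2. At day 4 itself neither gene was called between KO2 and KO1 (log2 −0.12 and 0.45, adjusted p = 0.688 and 0.0897). The responses of the clones were not tested against each other. Cholesterol synthesis genes gained in 18 of 19 cases (19 adjusted over the list alone), with a median of log2 0.74 and adjusted p = 0.0463 with an estimated correlation. In KO1 the gain had 18 of 19 called (19 adjusted over the list alone), a median of log2 1.52 and adjusted p = 0.00401 with an estimated correlation, while KO2 had 0 of 19 called, a median of log2 0.105 and adjusted p = 0.717. WNT pathway genes gained in 2 and lost in 6 of 26 cases (3 and 7 adjusted over the list alone), with a list call lost at adjusted p = 0.137 with an estimated correlation.

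In the clones themselves, primitive streak genes rose between the days in 18 of 20 cases, the same adjusted over the list alone, with a median of log2 5.28, or 4.91 with genes at 0 counts at their bound. Definitive endoderm genes rose in 32 and fell in 6 of 41 cases, also adjusted over the list alone, with a median of log2 2.25 (adjusted p = 0.0113 with an estimated correlation). Of 11195 features that passed, 5595 were higher and 5600 lower. With upper-quartile factors in place of TMM these were 4789 and 6264. Among 1296 features that rose in WT by at least 1 (log2), 75.1% rose less in the mean of the clones, with a median ratio of log2 changes of 0.718, and 353 were called smaller and 49 larger. The ratio was 0.899 in KO1, with 141 called smaller and 97 larger, and 0.545 in KO2, with 435 and 31. These features were chosen for their rise in WT, which by itself favours a smaller rise elsewhere. When features were chosen on WT replicate 1 and the clones compared with WT replicate 2, 68.6% of 1196 rose less in the clones, with a ratio of 0.781. The other way round it was 73.5% of 1071, with a ratio of 0.725. Of 1157 features chosen instead for their rise in the clones, 57.1% rose less in WT, with a ratio of WT to clones of 0.945.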

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

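The tests weighed here of the chromosome 20 genes, of cells left in the day 0 state and of an exchange of libraries were chosen only after the result was seen, the last in place of an earlier test on the chromosome 20 genes and after the values of 2 of its features (LRRC61 and PCDHGA10) had been seen.

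These results were set apart because a direct test showed 2 groups to differ in their effect. The effect of the knockout label differed between the days in 2288 features. Without 1 library that count was 1502 (WT day 0 replicate 1), 861 (WT day 0 replicate 2), 4721 (KO1 day 0 replicate 1), 3751 (KO1 day 0 replicate 2), 1503 (KO2 day 0 replicate 1), 1518 (KO2 day 0 replicate 2), 939 (WT day 4 replicate 1), 1401 (WT day 4 replicate 2) and 1492 (KO2 day 4 replicate 2). The difference between the days had a median of log2 −1.369 over definitive endoderm genes (−0.682 in KO1 and −2.12 in KO2) and 0.741 over cholesterol synthesis genes (1.518 in KO1 and 0.105 in KO2). The response of KO1 between the days differed from that of WT in 1645 features and that of KO2 in 2329.

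The clones differed from each other in 4214 features at day 4 and in 2 at day 0. The day 4 count was 2146 and 2789 without KO1 day 4 replicate 1 or 2, and 2667 and 2285 without KO2 day 4 replicate 1 or 2. At day 0 the 2 features, LRRC61 and PCDHGA10, were higher in KO2, named after their values were seen. DESeq2 called 2 and limma-voom 0 at day 0, and 648 had an unadjusted p under 0.05 in edgeR. That count was 0 without WT day 0 replicate 1 or 2, KO1 day 0 replicate 2, KO2 day 0 replicate 1 or 2 or KO1 day 4 replicate 1 or 2, 1 without WT day 4 replicate 1 or 2 or KO2 day 4 replicate 1 or 2, and 2746 without KO1 day 0 replicate 1. At day 4 the median of KO2 minus KO1 was 0.451 over pluripotency genes, −1.335 over primitive streak genes, −1.458 over definitive endoderm genes, −1.795 over mesoderm genes, −0.508 over BMP targets, −0.481 over genes of adhesion and epithelial-mesenchymal transition, −1.594 over cholesterol synthesis genes and −2.138 over replication histones.

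A run of 9 neighbouring genes on chromosome 20, from HM13 to TM9SF4 and with BCL2L1 and TPX2 in it, was higher in KO2 than in WT, with a median of log2 0.40 at day 0 (TPX2 and TM9SF4 called) and 0.428 at day 4 (8 of 9 called), and the 20q11 list fixed before was not called in KO2 at day 4 (adjusted p = 0.235) and was called at day 0 (adjusted p = 8.35e-07) but not with an estimated correlation (0.0548). Low WT libraries would leave the clones alike. The median of KO2 minus KO1 was 0.435 at day 4 (7 of 9 called) and 0.237 at day 0 (0 called). KO1 minus WT, which holds no KO2 library, was 0.074 at day 4, against 0.428 for KO2, and 0.158 at day 0. The run had been picked for being high in the same KO2 libraries, so the medians of KO2 minus KO1 decide the question at neither day. Its ends and length were chosen after values of both days were seen, so that its ranks are no test of chance or of handling of the day 0 cultures, and the run highest in KO2 against WT at day 0 was looked up at day 4 for each length from 3 to 31 genes instead. Of these 29 lengths, 12 had under 1% of other runs as high at day 4. A median over 0.1 (log2) and among the highest 2.5% of runs was seen at 13 (17 against KO1). At 3, 4 and 25 to 31 genes the run looked up lay elsewhere, such as UBR3 to GAD1, and says nothing of the chromosome 20 run. At 6 to 17 genes it overlapped that run, and 0.0883% to 0.844% of other runs were as high. At 5 genes the share was 1.19%, and at 18 to 24 genes, in runs reaching further out, 9.55% to 57%. The answer thus turned on the length, and neither is excluded. A gain of this region in KO2, or in part of its cells, may account for the run and is a hypothesis, since no DNA was measured.

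KO2 held less of the definitive endoderm transcripts at day 4 than KO1 and WT, with list medians against WT of log2 −2.155 in KO2 and −0.458 in KO1, and over 52 genes of any kind strongly induced in WT it had a median of 16% of the WT level against 72.5% in KO1. The 81 features with an unadjusted p under 0.01 between the clones at day 0 bear on an exchange of the clones' day 4 libraries. Of them 69.1% had the same sign at day 4, with 23 called in the same direction and 3 in the other. Chance alone would give as many features at that p among the 16792 tested, and only 2 passed the threshold at day 0. No background share was set beside these values, so they argue against an exchange only weakly. A share of cells left in the day 0 state, the rest being like WT, was tested first by the share of these 52 genes called above WT in KO2. That share was 3.85% (T and NODAL) and lay between the bounds set for it, so another test was chosen after it, in which 22 genes that fell strongly in WT stood at a median of 5.74% of their day 0 level in KO2 (3.46% in WT, 2.77% in KO1), although such cells would keep most of it. A slower or different path of KO2, a difference between clones other than DIGIT and the knockout itself stay open and were not told apart by these tests.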

How the results depend on the processing

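All settings given here were chosen before the data were examined, so no test of this part was chosen after a result was seen. No named gene that was called changed direction under any of them, and no gene or list was called in the direction opposite to its main result. Changes of sign that ended without a call were not counted for the other genes and lists. Of 409 named-gene values, all kept their side of the threshold with RLE size factors, 408 with upper-quartile factors, 408 with the replicate block, 401 without a filter, 396 with limma-voom and 388 of 407 with DESeq2, and all 407 with a strict filter. In a fit of only the libraries compared 297 of 307 kept theirs, with 4 calls ended and 6 made. Leaving out a library ended 99 calls and made 15, and the 4 KO libraries of a day as 1 group ended 121 of 239. Among 286 list results, called or not, the estimated correlation ended 71 calls, and fry ended 15 and made 45. Results not called at the preset correlation could not be ended, so these 71 were the larger part of the list calls. Upper-quartile factors moved the median of all genes by at most 0.083 (log2). Except where the construction of a setting shows it, the cause was not tested.

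With a fold change of at least 1 (log2), which by construction keeps fewer features, counts were 3080 for WT between the days (8332 without it), 3268 for KO between the days (11195), 163 higher and 458 lower for KO against WT at day 4 (1902 and 2109), 24 for KO against WT at day 0 (47), 553 for the difference between the days (2288), 670 for KO1 (3337) and 1066 for KO2 (4697) against WT at day 4, 24 for KO1 against WT at day 0 (40) and 1124 for KO2 against KO1 at day 4 (4214). Without a filter, counts were 232 for KO, 383 for KO1 and 113 for KO2 (24 with it) against WT at day 0, and 71 for KO2 against KO1 at day 0 (2). The larger part of these turned: 124 higher and 108 lower for KO (15 and 32 with the filter), 233 and 150 for KO1 (10 and 30), 60 and 53 for KO2 (9 and 15) and 14 and 57 for KO2 against KO1 (2 and 0). In a fit of only the libraries compared they were 21, 16 and 8 for KO, KO1 and KO2 against WT at day 0, 0 for KO2 against KO1 at day 0, 5410 for KO1 against WT at day 4, and 3055 higher and 3225 lower for KO against WT at day 4. With the 4 KO libraries as 1 group they were 18 for KO against WT at day 0, 341 for the difference between the days, and 779 higher and 954 lower for KO against WT at day 4. Features called with the same sign in both clones numbered 20 at day 0, and 633 higher and 831 lower at day 4. With limma-voom KO2 against KO1 at day 0 had 0.

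Lists called with an estimated correlation were 6 for WT between the days (11 at the preset one), 5 for KO between the days (10), 3 for KO against WT at day 4 (13), 2 for KO against WT at day 0 (8), 2 for the difference between the days (9), 2 and 1 for KO1 and KO2 against WT at day 4 (9 and 12), 1 and 3 for KO1 and KO2 against WT at day 0 (9 and 9) and 0 for KO2 against KO1 at day 0 (3). With fry they were 19 for WT and 22 for KO between the days, 5 for KO and 4 for KO1 against WT at day 0, 21 for KO2 against KO1 at day 4 (11) and 0 at day 0. The share of genes induced in WT with a smaller change in KO was 75.1% with a median ratio of 0.718. Values of the same kind were 68.6% and 0.781 for genes selected on WT replicate 1, with KO compared with WT replicate 2. For genes selected in KO, 57.1% rose less in WT, with a ratio of WT to KO of 0.945.

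Leaving out 1 library at a time gave these lowest and highest counts. They were 6477 (without WT day 4 replicate 1) and 9831 (without KO1 day 0 replicate 1) for WT between the days, and 10300 (KO2 day 0 replicate 2) and 12058 (KO1 day 0 replicate 1) for KO between the days. For KO against WT at day 4 they were 637 and 2902 higher and 1114 and 3146 lower, each without WT day 4 replicate 1 and without KO1 day 0 replicate 2. They were 12 (WT day 0 replicate 1 or 2) and 1657 (KO1 day 0 replicate 1) for KO against WT at day 0, 861 (WT day 0 replicate 2) and 4721 (KO1 day 0 replicate 1) for the difference between the days, 1353 (KO1 day 4 replicate 1) and 5228 (KO1 day 0 replicate 1 or 2) for KO1 and 2492 (WT day 4 replicate 1) and 6596 (KO1 day 0 replicate 2) for KO2 against WT at day 4. They were 9 (WT day 0 replicate 1 or 2) and 3787 (KO1 day 0 replicate 1) for KO1 and 2 (KO2 day 0 replicate 1) and 120 (KO1 day 0 replicate 2) for KO2 against WT at day 0, and 2146 (KO1 day 4 replicate 1) and 6120 (KO1 day 0 replicate 2) for KO2 against KO1 at day 4, and 0 and 2746 (KO1 day 0 replicate 1) at day 0. Leaving out either KO1 day 0 library takes the spread of that pair, the widest of the 6, out of the pooled error by construction, and the library left alone is assumed to vary like the other groups. That loss is alike for both libraries, so it does not by itself account for gaps between leaving out replicate 1 and replicate 2. In comparisons that hold KO1 at day 0, the highest counts came without replicate 1. Replicate 2, which stood apart, is then the only KO1 library of day 0. The replicate numbers showed no strong pairing of the libraries. The 15 correlations between groups of the difference between replicates ran from −0.0403 to 0.155 with a median of 0.0383, which does not exclude a weak one. The replicate block gave 8613 features for WT and 11433 for KO between the days, 4382 for KO against WT at day 4, 58 at day 0 and 2651 for the difference between the days, and changed 1 named call, LEFTY2 in KO2 against KO1 at day 4 (log2 0.46, adjusted p = 0.0377, with a range of 9.07e-05 to 0.486 over the alternatives).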

Other observations

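The test of other splits and that of list members below were chosen before the values were seen, and the histone genes were looked at because their list was called. Replication histone genes lay lower in KO2 than in KO1 at day 4. Of 14 measured, 10 were higher in KO1 than in WT and 0 lower (12 adjusted over the list alone), with a median of log2 1.34, and in KO2 0 were higher and 4 lower, with a median of log2 −0.72. The list calls against WT were lost at adjusted p = 0.0697 in KO1 and 0.404 in KO2 with an estimated correlation, while the direct comparison had 12 of 14 lower in KO2 than in KO1 (12 adjusted over the list alone) and adjusted p = 0.0284 with an estimated correlation. HIST1H1C was higher in KO1 by log2 0.93 and lower in KO2 by log2 −1.77. As background, messages of this kind mostly lack the poly(A) tail that these libraries select for, and close copies share reads. Cell cycle genes were higher in 5 of 25 cases in KO1, a list call lost at adjusted p = 0.498 with an estimated correlation, and in KO2 3 were higher and 2 lower (adjusted p = 0.925).

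Stress response genes were higher in KO1 than in WT at day 4 in 11 of 22 cases (14 adjusted over the list alone), with a median of log2 0.48 and a call lost at adjusted p = 0.0514 with an estimated correlation. In KO2 4 were higher and 1 lower (adjusted p = 0.366), and 12 of 22 were lower in KO2 than in KO1 (13 adjusted over the list alone; adjusted p = 0.0949 with an estimated correlation). Chromatin regulator genes were higher in 5 and lower in 2 of 22 cases in the mean of the clones at day 4 (adjusted p = 0.241), with the demethylase gene KDM6B lower by log2 −1.02, and HOX genes were measured in 4 of 29 cases with 0 called (adjusted p = 0.865). Germ cell genes were higher in 3 and lower in 4 of 13 cases (adjusted p = 0.0524), apoptosis genes higher in 6 and lower in 5 of 20 (adjusted p = 0.843), imprinted genes higher in 2 and lower in 4 of 21 (adjusted p = 0.371) and trophoblast and amnion genes higher in 1 and lower in 2 of 12 (adjusted p = 0.645). Ribosomal protein genes were higher in 5 of 28 cases, with a list call lost at adjusted p = 0.351 with an estimated correlation.

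The 8 KO libraries can be split into 4 and 4 in 35 ways. The real split by day gave 9394 features past the threshold in a fit of these libraries and the highest other split 0. Thus 1 of 35 splits, the real one, gave as many, the smallest share this test can give. Every other split puts libraries of both days on each side. The difference between the days then widens its spread, so few calls were bound to follow. The libraries are also pairs from 2 clones. Because the low counts of the other splits were bound to follow, no conclusion on chance is drawn from them, and chance is not excluded.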
